A study of Tetrahymena thermophila with 7 samples.

How the data were processed

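RNA-seq libraries were made from vegetative cells of *Tetrahymena thermophila* grown in rich medium, with poly(A) selection, random-primed cDNA and a library kit for which the labels give no strand step. The 7 libraries fall into 5 groups by the genotype in the labels: WT (2), UPF1a KO (2), MAG1 KO (1), SMG6L KO (1) and SMG6L NYN (1). The submitters' processing notes name CASAVA 1.8, TopHat2 2.0.9, Cufflinks 2.1.1, Cuffdiff, SAMtools and R 3.1.1 without giving each one's role, and the genome build is not given in the sources used here. Scaffold positions are those of the deposited files.

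The authors deposited whole-number read counts per exon part for the WT and UPF1a KO libraries, in a DEXSeq layout per the file headers. There a read that covers several parts is counted in each, and 3 lines without a gene were left out. The mean signal per part in that deposited table equals the plain mean of the 4 counts. The authors' DEXSeq p-values and adjusted p-values and their log2 fold of part usage, control over knockout, were taken as deposited and quoted as theirs. Per the file headers, FPKM values for genes and isoforms come in the Cuffdiff layout, with 1 value per group, which for WT and UPF1a KO covers both replicates, and the authors' q-values of their comparisons stand beside them. FPKM values are scaled for length and library size by the authors, and a gene listed at 0 can be a failed estimate. Whether the counting used strand is not given in the sources used here, so genes with an overlapping or antisense neighbour, and genes that share reads with a near copy, are uncertain.

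The counts cover 125686 parts of 24153 merged genes, and the libraries hold between 17941410 and 23032712 part counts. Counts were summed per gene. edgeR 4.0.16 (R 4.3.3) tested UPF1a KO against WT with TMM scaling, its default expression filter, the quasi-likelihood test and Benjamini-Hochberg adjustment at 0.05, without a block. Exon parts were tested with edgeR's exon-level test of differential usage. DESeq2 1.42.0 was the alternative tool, and limma 3.58.1 gave the camera test with a preset correlation of 0.01. Standard errors are those of the fitted log2 changes. Each part was classed from the transcripts in the deposited part table that hold it, as constitutive, terminal, cassette exon, retained intron, alternative splice site or other. FPKM comparisons used log2((mutant FPKM + 1)/(WT FPKM + 1)), and with 1 value per group no test was made: a gene counts as higher or lower at a difference of at least 1 with the higher value at least 5. Random lists (10000) were matched in 20 bins of mean expression. Unchanged groups (100) were simulated against the WT libraries with the spread measured between replicates, each library drawn independently of the others. Intervals for shares are 95% Wilson intervals, those for medians come from 1000 bootstrap draws over genes, and all cover sampling of genes or parts only.

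The gene FPKM tables and the isoform tables rest on different annotations, and 15742 of 23522 locus tags in the isoform table occur in the gene table. FPKM values were therefore joined to counts through the sum of isoform FPKM per merged locus (12164 loci), a choice made after a join by locus tag had reached 311 of the 610 genes higher in UPF1a KO. MAG1 has no count values under its locus tag here. All 26996 gene identifiers occur in the reference table of assembly JCVI-TTA1-2.2, which gives no names beyond the locus tags. The gene lists by product name that were fixed before the data were examined, lists for starvation, conjugation and stress included, thus matched 0 genes and were not tested. The groups, tests, size rule, alternatives and the rule for named genes were also fixed before the data were examined. That rule names the 3 targeted genes, the 3 highest and 3 lowest log2 changes per comparison (adjusted p under 0.05, replicates on the same side and at least 5 CPM for UPF1a KO, at least 10 FPKM for single libraries) and up to 10 exon parts with the smallest adjusted p, 1 per gene. Its further part, 10 genes each way with a product name, could not be filled. Since edgeR called 0 genes for UPF1a KO, the rule was applied to DESeq2 calls there, a choice made after seeing this.

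The tests were tested on simulated data with 200 changed genes or parts. At 10% of the measured dispersion edgeR recovered 94.4% of 4-fold changes with 18 calls among unchanged genes, and at a low dispersion, the same for every part, the exon-part test recovered 87% of 16-fold changes with 30 calls among unchanged parts. Alternatives covered scaling, filters, tool, thresholds, the replicate number as a block, each replicate left out, the pseudocount, median-centring, expression and length bins. Figures and remaining steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.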

Results

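Poly(A)-selected RNA from growing *Tetrahymena thermophila*, a ciliate that decays transcripts with premature stop codons, was sequenced in 7 libraries from 5 groups. These were wild type (WT, strain B2086, 2 libraries), a deletion of UPF1a (UPF1a KO, 2 libraries) and somatic knockouts of MAG1 and of SMG6L (MAG1 KO and SMG6L KO, 1 library each). The last group, SMG6L NYN (1 library), has a somatic truncation of the coding sequence of the NYN nuclease domain in SMG6L. Upf1 is the RNA helicase at the centre of nonsense-mediated decay, Mag1 is the counterpart of the exon junction complex protein Mago, and the NYN domain is a nuclease fold. Read counts per exon part (a stretch of exon bounded by splice sites or transcript ends) covered the WT and UPF1a KO libraries, with totals of 18778913 and 23032712 for WT and 17941410 and 21642052 for UPF1a KO. All 5 groups had FPKM values, 1 per group, whose depth is unknown. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these libraries, and 3 of the mutants have no replicate.

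The targeted genes were measured first. UPF1a (TTHERM_00726300, scaffold scf_8253904, 216023 to 220982, plus strand) was listed at 0 FPKM in UPF1a KO against 28.3 in WT, 41.0 in MAG1 KO, 48.2 in SMG6L KO and 51.1 in SMG6L NYN. In both UPF1a KO libraries exon parts 4 to 18 of its 20 parts held 0 reads, while the outermost parts kept reads, 119 and 23 in part 1 and 91 and 34 in part 20. Summed over all parts the gene had 24.1 and 4.07 CPM (read counts scaled to the size of each library) in the 2 UPF1a KO libraries and 92.7 and 77.4 in WT, a difference called by DESeq2 (adjusted p = 0.0259) and not by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.652). MAG1 (TTHERM_000476709) was listed at 0 in MAG1 KO and at 686 in WT, 568 in UPF1a KO, 506 in SMG6L KO and 493 in SMG6L NYN. SMG6L (TTHERM_00171790, scaffold scf_8254798, 378735 to 383693, minus strand) stood at 0.169 FPKM in SMG6L KO against 11.2 in WT, a difference of -3.38 on the log2(FPKM + 1) scale. Its value was 18.9 in SMG6L NYN, where only the coding sequence of a domain was truncated, so that gene value does not check the label of that library. SMG6L was at 26.3 FPKM in UPF1a KO, with 69.3 and 65.3 CPM in the 2 knockout libraries and 28.8 and 26.8 in WT. That difference, 1.27 on the log2 scale (SE 0.37), did not pass the edgeR test (adjusted p = 0.523) or DESeq2 (adjusted p = 0.461). In the authors' deposited table the q-values were 0.00936 for UPF1a in UPF1a KO, 0.00936 for MAG1 in MAG1 KO and 0.240 for SMG6L in SMG6L KO.

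**Figure D1:**
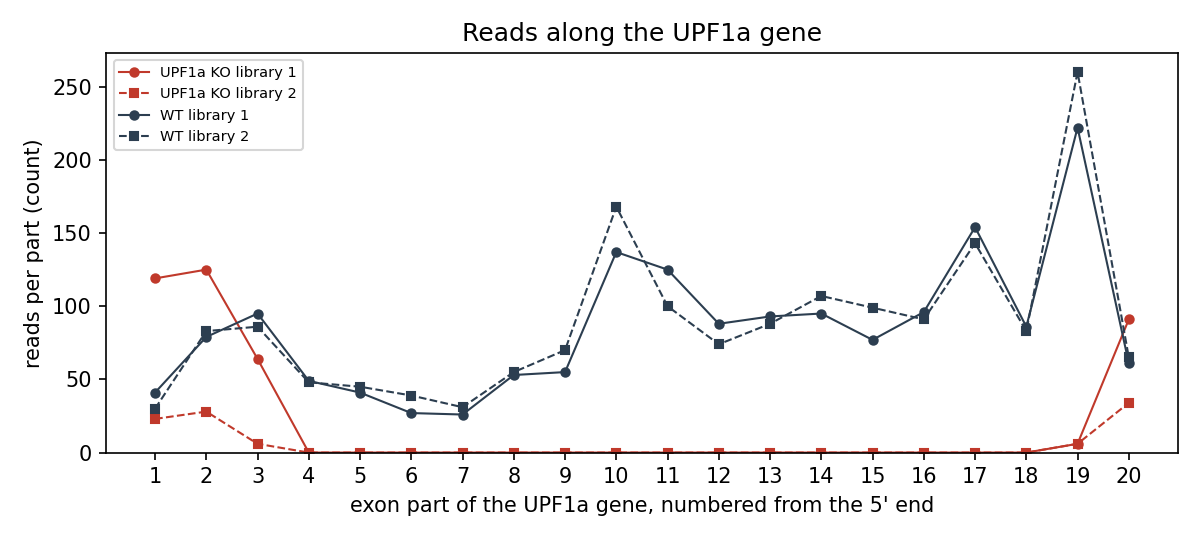
Reads per exon part (count, vertical axis) along the 20 parts of the UPF1a gene from its 5' end (horizontal axis), 1 line per library for 2 UPF1a KO and 2 WT libraries. Parts 4 to 18 hold 0 reads in both UPF1a KO libraries, and WT parts hold reads throughout.

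Loss of UPF1a went with a set of genes that were mostly higher, as called by DESeq2. DESeq2 called 341 genes higher and 61 lower of 17974 tested. Among the higher genes, XLOC_011244 (scf_8254564, 843767 to 845035, plus strand), a merged locus with no locus tag, reached 1320 and 668 CPM in UPF1a KO against 9.76 and 3.99 in WT, a log2 change of 7.15 (SE 0.64, DESeq2 adjusted p 5.15e-25). TTHERM_00858070 (scf_8254496, 85391 to 85810, plus strand), with no annotated intron, stood at 2665 and 1779 CPM against 11.9 and 3.90, a log2 change of 8.10 (SE 0.65, DESeq2 adjusted p 6.28e-32). Its FPKM, 14.1 against 1.92, was far smaller, so its size is uncertain. TTHERM_00853010 (scf_8254034, 227612 to 230356, plus strand) had 16.7 and 21.5 CPM against 0.109 and 0. Among the lower genes, TTHERM_00489440 (scf_8254636, 137511 to 138203, minus strand) had 0 reads in both knockout libraries against 10.03 and 47.2 CPM, TTHERM_00365370 (scf_8254813, 474744 to 486662, minus strand) had 0 against 8.34 and 28.7, and TTHERM_00750022 (scf_8254674, 264145 to 264844, plus strand) had 0.0595 and 0 against 21.6 and 26.2. Of genes with introns 293 were called higher and 28 lower by DESeq2 among 14285 tested, and of genes without introns 48 higher and 33 lower among 3689.

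These calls depended on the tool. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, the test fixed beforehand, called 0 genes at an adjusted p under 0.05 (smallest adjusted p = 0.141). At an unadjusted p under 0.05 it gave 1019 genes, 842 higher and 177 lower. The 899 expected by chance hold only if the libraries vary independently, which the correlations given below go against. The authors' deposited table marked 324 genes higher and 108 lower. Of the 402 DESeq2 calls 398 had an unadjusted edgeR p under 0.05. The spread between libraries was wide, with a biological coefficient of variation of 0.466. Same-numbered UPF1a KO and WT libraries correlated at r = 0.951 and 0.912 (log-CPM), libraries of 1 genotype at 0.928 (UPF1a KO) and 0.897 (WT). Some of the spread was thus common to same-numbered libraries, and fits with the number as a block are given with the alternatives below. In counts simulated with the measured spread of these 17974 genes edgeR recovered 6.54% of 4-fold and 73.1% of 16-fold changes. DESeq2 recovered 29.9% and 86.0% there but also called 52 genes that had not been changed, so its 402 calls hold an unknown share of false ones. Both UPF1a KO libraries lay on one side of both WT libraries in 27.7% of genes. Chance gives 33.3% only if the 4 libraries vary independently. The correlations above go against that, so the 2 shares cannot be compared. With a single library left out edgeR called 111 genes without UPF1a KO replicate 1, 122 without UPF1a KO replicate 2, 431 without WT replicate 1 and 350 without WT replicate 2, and DESeq2 144 (106 higher, 38 lower), 140 (106, 34), 490 (344, 146) and 222 (199, 23).

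Within genes, exon parts at alternative splice sites were the class in which the largest share rose in UPF1a KO. In the authors' deposited table of DEXSeq results, outside the UPF1a gene, 71 of 2515 alternative splice-site parts were higher in UPF1a KO (2.82%) and 9 were lower (0.358%). Retained introns had 12 higher and 5 lower of 1042, cassette exons 3 higher and 0 lower of 733, and parts shared by all transcripts 114 higher and 125 lower of 77092, in the authors' deposited table. By edgeR's exon-part test 15 parts of 66667 passed a Benjamini-Hochberg adjusted p of 0.05, 9 higher and 6 lower, 7 of them in the UPF1a gene itself (6 lower parts and part 1, which was higher) and 8 higher parts in 7 other genes, 4 of these at alternative splice sites. Higher and lower here mean the usage of a part relative to the rest of its gene. In reads, part 1 of UPF1a held 119 and 23 in UPF1a KO and 41 and 30 in WT. Part 4 of TTHERM_00628709 (scf_8254584, 8455 to 8596, 142 bases, plus strand) held 108 and 223 reads in UPF1a KO and 0 in both WT libraries (edgeR adjusted p 0.00483). Part 3 of TTHERM_00151340 (scf_8254545, 719073 to 719133, 61 bases, minus strand) held 94 and 161 reads against 3 and 5 (edgeR adjusted p 0.00782). Part 2 of TTHERM_00522720 (scf_8254664, 355566 to 355636, 71 bases, plus strand) held 615 and 480 reads against 22 and 14 (edgeR adjusted p 0.0170). All 3 are alternative splice-site parts.

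The other parts past edgeR's test were a part of 837 bases in TTHERM_00732890 (463 and 524 reads against 25 and 18), a 15-base and a 7-base part of TTHERM_01015930 (307 and 173 reads against 5 and 0, and 280 and 123 against 4 and 0), a 4-base part of TTHERM_00464970 (38 and 182 against 2 and 12) and a 1-base part of TTHERM_00628600 (16 and 24 against 0 and 0). The 7-base part, a further part of an already named gene, was added after its values were seen. In the UPF1a gene, TTHERM_00726300, part 10 held 0 reads in both knockout libraries and 137 and 168 in WT. Of 359 parts called in the authors' deposited table that edgeR also tested, 199 had an unadjusted edgeR p under 0.05 on the same side and 14 were called by edgeR. The edgeR calls fell to 0 without UPF1a KO replicate 1, without UPF1a KO replicate 2 or without WT replicate 2, and to 7 without WT replicate 1.

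The alternative splice-site parts that were higher in UPF1a KO seldom had a length divisible by 3, which would keep the reading frame, a comparison added after the parts had been seen. Of the 71 such parts in the authors' deposited table, 7 (9.86%) had a length divisible by 3, against 646 of 2435 parts (26.5%) that were not called (odds ratio for a length not divisible by 3 of 3.30, 95% interval 1.45 to 6.65, two-sided Fisher's exact p = 0.00088). By edgeR at an unadjusted p under 0.05, 6 of 77 higher parts had a length divisible by 3 (odds ratio 4.42). Of the 9 splice-site parts that were lower, 0 had such a length (two-sided Fisher's exact p = 0.123), so the scarcity is not shown to belong to the higher parts alone, and of 12 higher retained introns 2 did (16.7%), against 31.6% of those not called (two-sided Fisher's exact p = 0.359). The isoforms that hold the 64 called parts of other lengths made up a median of 13.3% of their locus FPKM in WT, 46.0% in UPF1a KO, 16.9% in MAG1 KO, 31.0% in SMG6L KO and 36.3% in SMG6L NYN. Their share was above WT for 57 of 64 parts in SMG6L KO (89.1%, 95% Wilson interval 79.1 to 94.6), 59 of 64 in SMG6L NYN (92.2%, 83.0 to 96.6) and 39 of the 62 that moved in MAG1 KO (62.9%, 50.5 to 73.8). The parts had been chosen against the same WT, which alone favours a rise over it; without WT, 56 of 64 were above MAG1 KO in SMG6L KO and 59 of 64 in SMG6L NYN. For TTHERM_00313780 the isoform with a 5-base part took 16.9% of the locus in WT, 73.9% in UPF1a KO, 12.8% in MAG1 KO, 56.9% in SMG6L KO and 67.3% in SMG6L NYN, and for TTHERM_00891200 the isoform with a 4-base part took 24.4%, 83.1%, 25.2%, 64.5% and 67.6% in that order. Both were chosen after their values were seen. The isoforms of the 7 called parts with a length divisible by 3 were also above WT in 6 of 7 cases in SMG6L KO and 7 of 7 in SMG6L NYN.

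**Figure D2:**
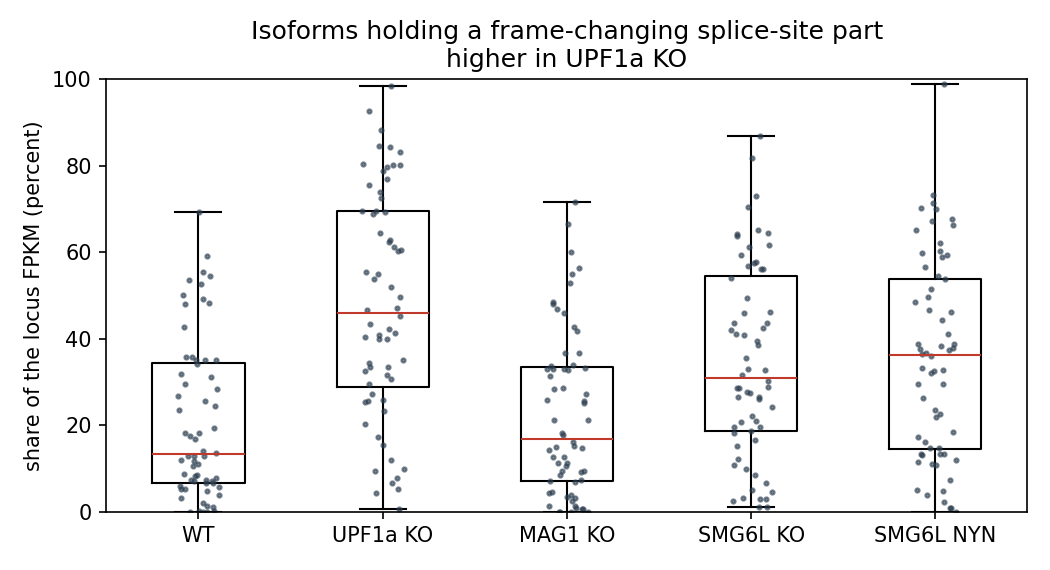
Share of locus FPKM (percent, vertical axis) taken by isoforms with one of the 64 alternative splice-site parts that were higher in UPF1a KO and whose length is not divisible by 3, 1 point per part in each of the 5 groups, with boxes for the quartiles, a line for the median and whiskers up to 1.5 times the box. Medians were 13.3% in WT and 16.9% in MAG1 KO, and 46.0%, 31.0% and 36.3% in UPF1a KO, SMG6L KO and SMG6L NYN.

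In MAG1 KO, by the rule of size fixed beforehand (a difference of at least 1 on the log2(FPKM + 1) scale with the higher value at least 5 FPKM), 1597 genes were higher and 1279 lower of 13299 compared. The rule is not a test, and at 1.5-fold 3166 genes were higher and 3181 lower. The authors' deposited table marked far fewer genes in each single-library mutant, more of them lower than higher, from tests with 1 mutant library. The gene farthest above WT was TTHERM_01104960 (scf_8254092, 68581 to 70219, minus strand), at 99.9 FPKM against 1.97 in WT and 2.63, 0.615 and 1.58 in UPF1a KO, SMG6L KO and SMG6L NYN. TTHERM_00951920 was at 0.0540 FPKM against 450 in WT and 166, 487 and 349 in UPF1a KO, SMG6L KO and SMG6L NYN. TTHERM_000849489 and TTHERM_000431329 were listed at 0 in WT and at the identical 25.5 FPKM in MAG1 KO. In SMG6L KO they differed, with 0 for TTHERM_000849489 and 42.3 for TTHERM_000431329. In groups simulated as unchanged against the same WT libraries, with the spread measured between replicates over 12164 loci, the rule gave on average 798 higher and 1121 lower loci where MAG1 KO had 1382 and 1099. Only its higher count exceeded the simulated one. The simulated counts may be too large, because libraries were drawn independently, so they do not show that the lower count is no more than chance gives. Across the 12164 loci the difference of MAG1 KO from WT correlated with the difference between the 2 UPF1a KO libraries (replicate 2 over replicate 1) at r = 0.62, and that of SMG6L KO and SMG6L NYN at 0.48 and 0.49. Scaling each comparison to a median of 0 (shifts of -0.11 in MAG1 KO, -0.11 in SMG6L KO and -0.13 in SMG6L NYN) changed the share of higher genes in MAG1 KO from 55.5% to 66.1%.

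In SMG6L KO 460 genes were higher and 1202 lower of 13144. TTHERM_00586620 (scf_8254580, 27259 to 29592, minus strand) was at 2.62 FPKM against 561 in WT, and it was also low in UPF1a KO (27.0), MAG1 KO (21.2) and SMG6L NYN (18.0). TTHERM_02650290 (scf_8255745, 54 to 308, minus strand) was listed at 0 in SMG6L KO and at 123 in WT, 81.4 in UPF1a KO, 87.2 in MAG1 KO and 372 in SMG6L NYN. The genes farthest above WT, TTHERM_000431329 (42.3 FPKM), TTHERM_00760560 (25.05) and TTHERM_000676962 (21.2), were all listed at 0 in WT. Unchanged simulated groups gave 791 higher and 1115 lower loci where SMG6L KO had 362 and 981. Neither count exceeded the simulated one, which may be too large because libraries were drawn independently. With the median at 0 the share of higher genes was 38.3% in place of 27.7%.

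In SMG6L NYN 590 genes were higher and 1101 lower of 13262. TTHERM_00351140 was at 2.61 FPKM against 759 in WT and was also low in UPF1a KO (6.10), but stood at 238 in MAG1 KO and 381 in SMG6L KO. TTHERM_00619860 (scf_8254605, 72918 to 74248, minus strand) had the same profile, with 1211 in WT, 5.71 in SMG6L NYN, 7.03 in UPF1a KO, 547 in MAG1 KO and 575 in SMG6L KO. TTHERM_00895830 (scf_8254707, 100137 to 100325, minus strand) was among the lowest genes in all 3 single-library mutants, at 5889 FPKM in WT and 36.7, 19.8, 57.7 and 8.32 in UPF1a KO, MAG1 KO, SMG6L KO and SMG6L NYN. TTHERM_001549939 (30.7 FPKM), TTHERM_00550940 (21.6) and TTHERM_000724801 (18.7), the farthest above WT, were listed at 0 in WT. Unchanged simulated groups gave 794 higher and 1125 lower loci where SMG6L NYN had 448 and 968, and these simulated counts may be too large for the reason given for SMG6L KO. With the median at 0 the share of higher genes was 49.7% in place of 34.9%.

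Genes that were higher in UPF1a KO were mostly also above WT in both SMG6L mutants, while in MAG1 KO their median lay close to WT. The same rule put 610 genes at least 2-fold higher in UPF1a KO. Of these, 219 (35.9%) were at least 2-fold higher in SMG6L KO, 264 (43.3%) in SMG6L NYN and 84 (13.8%) in MAG1 KO. Random lists matched on expression gave 5.34%, 8.07% and 12%, but they do not carry the shared WT. Loci higher in both numbered 162, 204 and 53 in that order, against 182, 182 and 183 simulated for unchanged groups with a shared WT. Unchanged groups simulated for UPF1a KO gave 545 higher and 546 lower loci where 531 and 366 were observed. The simulation drew every library independently, while same-numbered libraries varied together, so its spread may be too wide. It thus cannot show whether the list is longer than chance gives. The median log2 difference of the 610 genes was 0.68 in SMG6L KO, 0.88 in SMG6L NYN and -0.12 in MAG1 KO. TTHERM_00393110 (scf_8254719, 301483 to 304531) stood at 10.2 FPKM in WT, 205 in UPF1a KO, 117 in SMG6L KO, 127 in SMG6L NYN and 15.5 in MAG1 KO, and TTHERM_01281660 at 2.96, 117.8, 39.7, 36.9 and 5.50 in that order. TTHERM_00102850 was listed at 0 in WT and in MAG1 KO and at 8.95, 10.4 and 10.5 in UPF1a KO, SMG6L KO and SMG6L NYN. Of 152 genes higher in UPF1a KO, SMG6L KO and SMG6L NYN, 114 (75%) were not past 2-fold in MAG1 KO. The other 38 were higher in all 4 mutants. Of all genes with an FPKM of at least 5 in a group, 11.5% were at least 2-fold higher in MAG1 KO. The 152 genes were higher there more often, not less, than genes in general. They had been chosen against the same WT, which alone favours a rise over it, so their excess in MAG1 KO cannot be told apart from that choice. Among the 38 were TTHERM_00419690 (49.3 FPKM in WT and 408, 189, 657 and 692 in UPF1a KO, MAG1 KO, SMG6L KO and SMG6L NYN), TTHERM_00711900 (4.18 and 32.3, 39.4, 36.4 and 32.8) and TTHERM_00129500 (1.02 and 15.97, 9.86, 9.01 and 13.4).

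Genes lower in UPF1a KO were often also below WT in the other mutants, MAG1 KO included. Of these 472 genes 229 (48.5%) were at least 2-fold lower in MAG1 KO, 317 (67.2%) in SMG6L KO and 297 (62.9%) in SMG6L NYN. Matched random lists gave 12.2%, 11.2% and 9.48% in that order. For MAG1 KO the shared lower loci numbered 176, against 168 simulated with a shared WT. The same simulation gave 183 shared higher loci where 53 were observed, so it cannot tell how much a shared WT gives here. Of 243 genes lower in UPF1a KO, SMG6L KO and SMG6L NYN, 175 were lower in all 4 mutants. The other 68 (28.0%) were not past 2-fold in MAG1 KO. Among the 175, TTHERM_000220919 was listed at 24.7 FPKM in WT and at 0 in each mutant. Among the 68, TTHERM_000079489, at 39.5 in WT and 36.2 in MAG1 KO, was listed at 0 in UPF1a KO, SMG6L KO and SMG6L NYN. Also among them, TTHERM_001561059 had 81.6 FPKM in WT, 53.3 in MAG1 KO and 16.8, 4.14 and 8.19 in UPF1a KO, SMG6L KO and SMG6L NYN, and TTHERM_000557969 had 131 in WT, 106 in MAG1 KO and 28.5, 30.0 and 14.1.

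All of these comparisons share the WT libraries, which alone makes differences correlate. Across 12164 loci, which are not independent replicates, the log2 differences of UPF1a KO correlated with those of SMG6L KO at r = 0.52 and of SMG6L NYN at r = 0.58, against simulated values of 0.40 and 0.41 for unchanged groups, and with MAG1 KO at r = 0.19 against 0.40. The covariance lay above the simulated one by 0.061 for SMG6L KO and 0.087 for SMG6L NYN, and below it for MAG1 KO (-0.078). SMG6L KO and SMG6L NYN correlated at 0.82, MAG1 KO and SMG6L KO at 0.67 and MAG1 KO and SMG6L NYN at 0.66, against 0.33 simulated for each. Loci higher in UPF1a KO and in SMG6L KO numbered 162, where independent lists give 16.5 and unchanged groups with a shared WT 182; the numbers were 204, 20.3 and 182 for SMG6L NYN and 53, 61.4 and 183 for MAG1 KO. Loci lower in both numbered 247 for SMG6L KO, 241 for SMG6L NYN and 176 for MAG1 KO, against 30.8, 30.3 and 33.6 for independent lists and 169, 169 and 168 simulated. With 2 WT libraries the control could not be split, and part of any excess may come from it. The simulation drew libraries independently, and MAG1 KO fell below it for r, covariance and shared higher loci, so it may overstate a shared WT. A comparison that uses no WT value, SMG6L KO over MAG1 KO, had a median of 0.65 on the log2 scale in the 610 genes. It was 0.77 for SMG6L NYN over MAG1 KO, and each lay above all 10000 matched random lists. So did SMG6L NYN over SMG6L KO, at 0.16, although both are mutants of the same gene. Passing all random lists is thus not particular to comparisons with MAG1 KO.

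**Figure D3:**
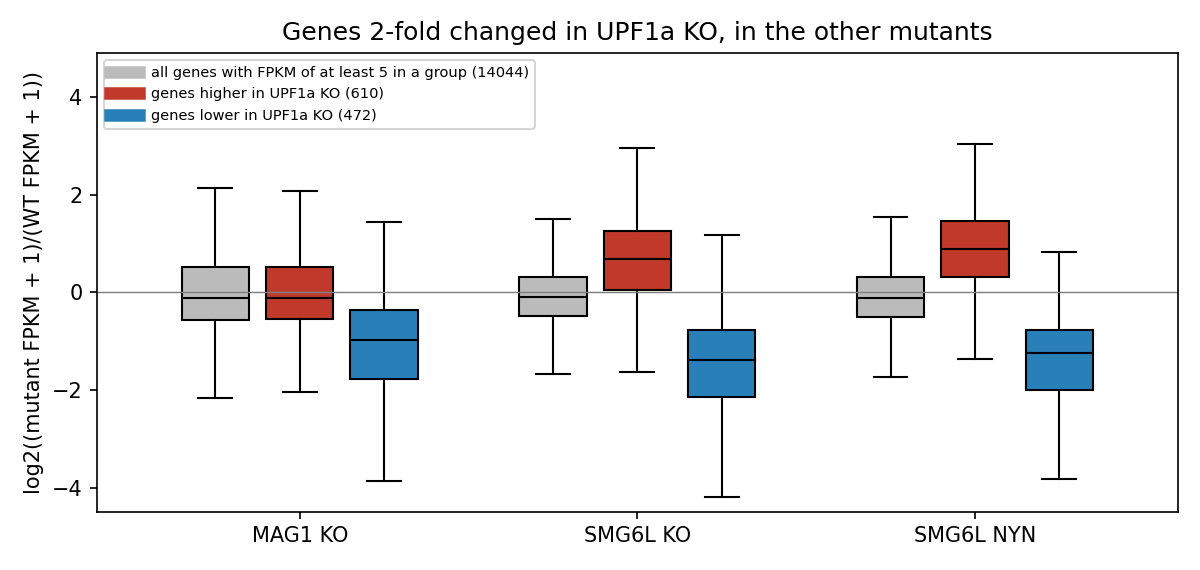
Difference from WT on the log2(FPKM + 1) scale (vertical axis) in MAG1 KO, SMG6L KO and SMG6L NYN for all genes with an FPKM of at least 5 in a group, the 610 genes higher and the 472 genes lower in UPF1a KO, with boxes for the quartiles, a line for the median and whiskers up to 1.5 times the box. The higher genes have medians of -0.12, 0.68 and 0.88 from left to right, and every difference uses the same WT values.

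Isoforms were compared between merged loci without and with a locus tag. Of 579 isoforms without one, 85 (14.7%, 95% Wilson interval 12.03 to 17.8) were at least 2-fold higher in UPF1a KO, against 799 of 13432 with one (5.95%, 5.56 to 6.36). The shares were 9.32% and 4.38% in SMG6L KO, 9.67% and 4.97% in SMG6L NYN, and 10.2% and 12.5% in MAG1 KO. At least 2-fold lower were 5.87% (4.23 to 8.09) without and 4.04% (3.72 to 4.39) with a tag in UPF1a KO, whose intervals overlap, 17.9% (14.9 to 21.3) and 12.3% (11.8 to 12.9) in MAG1 KO, 15.9% (13.1 to 19.2) and 11.2% (10.7 to 11.8) in SMG6L KO, and 18.98% (15.9 to 22.5) and 11.5% (10.96 to 12.04) in SMG6L NYN. None of these differences was tested. An isoform's share of its locus moved by at least 20 percentage points in 315 of 3492 loci in UPF1a KO, 378 of 3349 in MAG1 KO, 411 of 3442 in SMG6L KO and 397 of 3453 in SMG6L NYN. The intervals cover sampling of isoforms only, and there is 1 value per group. That value covers 2 libraries for UPF1a KO and 1 for each other mutant, so the shares are not comparable between UPF1a KO and the others.

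Genes without introns were compared with genes with them because the exon junction complex is left at spliced junctions. For UPF1a KO this used edgeR log2 changes of counts in 3689 genes without and 14285 with introns. For the other mutants it used differences on the log2(FPKM + 1) scale in 2605 and 9596 genes. Sizes are thus not comparable between UPF1a KO and the others. Genes without introns were more often at least 2-fold lower, 7.81% against 3.87% in UPF1a KO, 13.8% against 7.06% in SMG6L KO, 12.2% against 7.11% in SMG6L NYN and 11.5% against 8.99% in MAG1 KO, and these shares were not tested. They were at least 2-fold higher in 6.61% against 8.10% in UPF1a KO, 4.03% against 3.11% in SMG6L KO, 4.95% against 3.78% in SMG6L NYN and 12.9% against 11.005% in MAG1 KO. DESeq2 called 0.895% of genes without introns and 0.196% of genes with introns lower in UPF1a KO. The medians lay closer together. In UPF1a KO the median log2 change was -0.09 in 3689 genes without introns and -0.01 in 14285 genes with them, a gap of -0.08 (95% bootstrap interval over genes -0.10 to -0.06). limma's camera test gave p = 0.0283 for genes without introns, adjusted p = 0.113 over 4 structure groups, and adjusted p = 0.323 with an estimated correlation, so none was called. The gap was 0.08 in MAG1 KO (0.04 to 0.11), -0.07 in SMG6L KO (-0.11 to -0.04) and -0.07 in SMG6L NYN (-0.10 to -0.03). Within bins of gene length it was -0.04 in UPF1a KO and 0.21 in MAG1 KO, and its direction turned in SMG6L KO (0.01) and SMG6L NYN (0.03).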

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

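Of the alternatives, 48 kept a value on its side or within its interval or 1.5 times its count, 59 moved it and 3 reversed it; the DESeq2 runs with a replicate left out, the DESeq2 list, the join by locus sums and the removed replicate trend were chosen after the data were seen, and the cause of the moves was not tested unless given. The planned gene lists were not run, since they matched 0 genes. For UPF1a KO against WT, edgeR's 0 genes became 37 with no filter, DESeq2 gave 402, and 432 genes were marked in the authors' deposited table. With one replicate left out edgeR gave 111 to 431 genes, the lone library being assumed to vary like the other group, and DESeq2 140 to 490. Exon-part calls went from 15 to 9 with a minimum of 10 reads, to 0 to 7 with one replicate left out, and to 444 in the authors' deposited table. With the replicate number as a block edgeR called 485 genes (422 higher) and 102 parts, and the biological coefficient of variation was 0.256. Deviations of same-numbered libraries correlated at 0.63 across genes. With 2 pairs and no label for what a number stands for, the numbers do not establish a pairing.

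With a pseudocount of 0.1 SMG6L stood at -5.39 in SMG6L KO and 1.23 in UPF1a KO on the log2 scale. A 1.5-fold rule, looser by construction, called 6347, 4365 and 4596 genes in MAG1 KO, SMG6L KO and SMG6L NYN, and a minimum of 20 FPKM, which leaves fewer genes, 1006 in SMG6L KO and 1076 in SMG6L NYN. The share of genes higher in UPF1a KO that were higher in MAG1 KO, SMG6L KO and SMG6L NYN was 18.5%, 40.6% and 49.0% with a pseudocount of 0.1 and 25.8%, 44.9% and 52.3% at 1.5-fold. It was 6.01%, 51.1% and 55.8% for the genes called higher by DESeq2, of which only 233 of 341 reached 5 FPKM. On isoform FPKM summed per locus (576 loci) it was 10.1% in MAG1 KO and 43.4% in SMG6L NYN. On the 531 of these loci with counts it was 10.7% and 43.7%, and with the replicate trend removed there as well 9.79% and 38.6%. Most of the move in MAG1 KO thus came with the switch to locus sums, which also changed the annotation and the list. Median-centred the share was 49.0% in SMG6L NYN. For genes lower in UPF1a KO the shares were 80.0%, 76.0% and 88.0% in the DESeq2 list (50 of 61 genes), 67.5% in SMG6L KO and 65.8% in SMG6L NYN on joined locus sums (366 loci) and 56.8% and 58.2% there with the trend removed, and 57.8% in SMG6L NYN median-centred.

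Isoforms at loci with a locus tag were higher in 6.49%, 14.3%, 5.30% and 6.08% (UPF1a KO, MAG1 KO, SMG6L KO, SMG6L NYN) with a pseudocount of 0.1, and in 4.75%, 14.7%, 3.39% and 3.78% at 20 FPKM or more, where loci without a tag gave 11.1%, 5.54% and 7.19% in UPF1a KO, SMG6L KO and SMG6L NYN. The gap between genes without and with introns was -0.0382 in UPF1a KO, 0.212 in MAG1 KO, 0.00639 in SMG6L KO and 0.0256 in SMG6L NYN within length bins, and 0.183, 0.00790 and -0.00538 in MAG1 KO, SMG6L KO and SMG6L NYN among genes above the median expression, so its direction reversed in SMG6L KO under both and in SMG6L NYN within length bins. Depth limits the UPF1a KO test less than the spread between libraries does: simulated 4-fold changes were recovered by edgeR in 94.4% of cases at 10% of the measured dispersion and in 6.54% at the full one.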

Other observations

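Genes lower in UPF1a KO lay side by side in the genome more often than shuffled calls do. Among the 61 genes called lower by DESeq2 there were 5 adjacent pairs, where 10000 shuffles gave 0.20 on average and at most 3, and among the 341 called higher there were 44, where shuffles gave 6.27 on average and at most 17. On scaffold scf_8254605 the minus-strand genes TTHERM_00619843, TTHERM_00619860, TTHERM_00620900 and TTHERM_00620923 (70083 to 91210) were called lower, TTHERM_00619860 with 3.75 and 3.11 CPM in UPF1a KO against 441 and 794 in WT, and TTHERM_00620900 with 4.70 and 3.19 against 208 and 191. By locus FPKM TTHERM_00620900 stood at 241 in WT, 5.64 in UPF1a KO and 2.19 in SMG6L NYN, but at 51.9 in MAG1 KO and 98.2 in SMG6L KO. On scaffold scf_8254692 TTHERM_01499930, TTHERM_01499940 and TTHERM_01499950 (9038 to 12878) were called lower, and TTHERM_01499940 had 4.70 and 3.69 CPM against 187 and 212, with locus FPKM of 11.3 in UPF1a KO, 572 in WT, 255 in MAG1 KO, 529 in SMG6L KO and 164 in SMG6L NYN. This count of neighbours was made after the calls had been seen.

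Of the tests that follow, those of read coverage and of short parts were set before their results were seen, and the others, on isoform shares, the shared WT, replicate libraries, shared transcripts, depth, length and batch, were chosen or run on a widened set of loci after first results had been seen. The first pattern is the scarcity of lengths divisible by 3 among alternative splice-site parts higher in UPF1a KO. Read coverage is argued against by an odds ratio of 3.39 (95% interval 1.55 to 7.39) within strata of mean count, and miscounting of very short parts by 2.75 (1.11 to 5.97) among parts of at least 6 bases. Loss of decay of frame-shifted transcripts stays an open hypothesis: 89.1% of the isoforms with such parts took a larger share in SMG6L KO than in WT, but the parts had been chosen against that same WT, and without WT 87.5% were above MAG1 KO, against 50.3% for parts of such lengths that were not called. The called parts with a length divisible by 3 moved the same way in 6 of 7 cases, so the isoform shares do not separate frame from being called, and stop codons were not searched because no genome sequence was used here.

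The second pattern is that genes higher in UPF1a KO were above WT in both SMG6L mutants and hardly in MAG1 KO. A shared WT as the whole cause is argued against by the median of 0.65 in SMG6L KO over MAG1 KO, a comparison without WT values. That argument rests on its size, since SMG6L NYN over SMG6L KO also passed all random lists, at 0.16. The difference between replicate libraries as the whole cause is argued against by a median of 0.65 in SMG6L KO after its trend was removed, on 531 of 576 loci, though the same test on the 311 of 610 genes (51.0%) first joined by locus tag gave 0.47, between the bounds of 0.3 and 0.5 set for it. That Upf1a and Smg6L act on the same transcripts and Mag1 does not stays an open hypothesis: the median of SMG6L NYN over MAG1 KO, 0.77, restates the pattern and does not test it. Each of these mutants is 1 library, so a batch that sets MAG1 KO apart stays open.

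The third pattern is that loci which differ between the 2 UPF1a KO libraries (replicate 2 over replicate 1) differ in the same way between MAG1 KO and WT, with a correlation across 12164 loci of 0.62. For SMG6L KO, SMG6L NYN and UPF1a KO it was 0.48, 0.49 and -0.03. With the difference between the 2 WT libraries, MAG1 KO, SMG6L KO, SMG6L NYN and UPF1a KO correlated at 0.43, 0.20, 0.26 and -0.29. Gene length bias as the whole cause is argued against by 0.59 for MAG1 KO with the UPF1a KO library difference after removing a length trend. Library depth stays open, since thinning the deeper UPF1a KO library to the other hardly moved any correlation (0.62 again for MAG1 KO) and the depth of the single-library mutants is unknown. Culture state or batch may lie behind it and cannot be told apart from genotype in the single-library mutants, because no label gives a batch.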
